A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

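Poly(A) RNA was sequenced from Saccharomyces cerevisiae trm10∆ spheroplasts in 6 groups, given by the electroporated RNA (none, rancRNA_18 or rancRNA_18-M2) and by the fraction (total mRNA, or mRNA from the pooled polysomal part of a density gradient). Libraries were made with a kit that keeps strand information, per the labels' protocols. FastQC, HISAT2 and featureCounts are named per the submitters' processing notes. Their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap another gene or an antisense partner, and members of near-identical pairs such as many ribosomal protein genes, are uncertain at the level of the single gene. The deposited files hold raw read counts per gene, 1 library per file, with no normalization by the authors. Each file lists 7126 genes and at most 1 line without a gene name, which holds no value. No spike-in is named in the labels, so all values are relative abundances within a library, and a change in the total amount of mRNA or of polysomes was not measured.

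Gene IDs were matched to locus tags of the RefSeq assembly R64, used for names, coding length, GC content and neighbouring genes only. Of the 7126 IDs, 6048 matched and 1078 did not. The unmatched IDs held at most 0.11% of the reads of a library. Groups and replicate numbers came from the sample titles.

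The 16 deposited files were compared within each group before any averaging. The pair of rancRNA_18 polysomal files, labelled as replicates 1 and 2, held equal counts in all 7126 genes, while every other pair within a group differed in 6404 to 6533 genes. They were counted as 1 library, which leaves 15 distinct libraries and n = 1 for this group, against the 16 libraries that the planned design assumed. Which replicate number that library carries cannot be read from the labels, so fits that use the number were run with it as 1 and as 2. A group of 1 library has no spread of its own: its comparisons borrow the spread pooled over the other groups, and that library is assumed to vary as they do.

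Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test (robust), with TMM scaling, the filterByExpr filter on the 6 groups and 1 coefficient per group. A total of 6106 genes were tested in each of 12 contrasts, and Benjamini-Hochberg adjusted p under 0.05 counted as a call. At most 9 residual degrees of freedom were available, and 7 with the replicate number as a block. Levels are CPM, counts scaled to the size of the library, and log CPM for the principal components used a prior count of 2. Scaling by DESeq2-style size factors in place of TMM moved the median log2 fold change of a contrast from -0.058 to -0.028 for polysomal against total mRNA with rancRNA_18, and from -0.021 to 0 for the same comparison with no RNA.

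The replicate numbers in the titles were checked for pairing. Deviations from the group means correlated in all 26 pairs of libraries with the same number but different group (r from 0.429 to 0.794, median 0.5845, all over 0.1), and ran from -0.587 to 0.03 in the 52 pairs with different numbers. All 14 libraries that could be scored correlated best with a library of their own number. The pairing therefore comes from the data and not from a statement in the labels. The planned fit without the block remains the starting point, and the value with the replicate block stands beside a result where it changes a call or moves a count by more than 1.5 times. Without the block, the spread between numbers stays in the error. An unadjusted p under 0.05 was then reached by 7 to 39 genes per contrast between electroporations. That is fewer than the share of 0.05 that unchanged genes would give by chance. Counts of 0 without the block are thus no evidence that nothing differed. In the comparison of polysomal with total mRNA the blocked fit supplies the named genes in addition.

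Genes were named by a rule fixed before the data were examined: TRM10 in every library, then, by contrast, up to 12 or 5 genes per direction with the largest change among those past the threshold, with a mean of at least 20 CPM and, outside the ratio contrasts, with every library of 1 group above every library of the other. Where none passed, the 3 genes with the smallest p in each direction at 20 CPM or more are given as values. Up to 4 members with the smallest p are named per list. Using the same rule on the blocked fit, with the same direction in every pair in place of separated groups, was chosen after seeing the data. Gene lists, 33 in number, were also fixed beforehand, and 32 had tested members. They were tested by camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation and by fry, which tests whether a list moves on balance 1 way without comparing it with other genes. Adjustment was over the 32 lists of a contrast.

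Recovery of known changes was tested on simulated data for the contrasts of group means. Counts were drawn for the real genes and libraries, with the replicate numbers and their spread as fitted, and with 100 genes changed 1.5-fold and 100 changed 2-fold. For rancRNA_18 against no RNA in total mRNA (6067 genes), 2% of the 1.5-fold and 20% of the 2-fold changes were recovered without the block, and 62.6% and 87% with it. The same simulation for rancRNA_18-M2 against no RNA gave 2% and 33% without the block in total mRNA (6072 genes), 75.8% and 91% with it, and in polysomal mRNA (6070 genes) 1% and 38.8%, then 80% and 90.8%. For rancRNA_18 against no RNA in polysomal mRNA (6074 genes) it gave 0% and 0%, then 31% and 81.8%. Polysomal against total mRNA with no RNA (6068 genes) gave 1% and 24.2%, then 76.8% and 89.9%, and with rancRNA_18 (6070 genes) 0% and 0%, then 29.6% and 74.5%. Without the block 0 unchanged genes were called. With it, false calls were 16 of 165 and 13 of 179 in total mRNA for rancRNA_18 and rancRNA_18-M2 against no RNA, and 5 of 117 and 11 of 180 in polysomal mRNA. For polysomal against total mRNA they were 6 of 171 with no RNA, 3 of 105 with rancRNA_18 and 11 of 169 with rancRNA_18-M2. For rancRNA_18 against rancRNA_18-M2 they were 6 of 165 in total and 9 of 127 in polysomal mRNA. The share was over the nominal 0.05 in 5 of these contrasts: rancRNA_18 against no RNA in total mRNA, rancRNA_18-M2 against no RNA in both fractions, rancRNA_18 against rancRNA_18-M2 in polysomal mRNA, and polysomal against total mRNA with rancRNA_18-M2. Each contrast had a single simulated set, so these shares and the recovered percentages vary by chance. A share over 0.05 in a single set does not show that the error control failed.

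Alternatives fixed beforehand were DESeq2 1.42.0, DESeq2-style size factors in edgeR, no filter on low counts, only the groups compared, the replicate block, a block for each culture (electroporation by number), and leaving out each library in turn. The shared rancRNA_18 polysomal library was not left out, since its group would be empty. Added after seeing the data were the shared library as number 2, the removal of length and GC trends, both of its copies counted, the blocked fit as the starting point for polysomal against total mRNA, and a simulation of shared controls that includes the numbers. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Mitochondrially encoded genes had no tested members, with at most 25 reads in a library, and are left out.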

Results

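The data describe yeast in which TRM10, the gene of a tRNA methyltransferase, was deleted (trm10∆). Spheroplasts, cells freed of their wall, were electroporated without RNA, with rancRNA_18, a short noncoding RNA that associates with ribosomes and derives from the TRM10 mRNA, or with rancRNA_18-M2, whose difference from rancRNA_18 is not given in the sources used here. After recovery, poly(A) mRNA was sequenced from the whole lysate (total) and from pooled polysomes, the ribosome-bound mRNA collected from a density gradient. There were 3 total and 3 polysomal libraries with no RNA, 3 and 3 with rancRNA_18-M2, and 2 total libraries with rancRNA_18. The 2 polysomal files deposited for rancRNA_18 were identical in every gene and were counted as 1 library, so that group has no replicate. Libraries held 16691019 to 31148081 reads in genes. The highest was replicate 3 of the polysomal libraries with no RNA, and the next held 21962246. Between 6331 and 6486 genes had reads. The most abundant gene took 1.91 to 2.98% of the reads of a library.

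TRM10 had 0 to 5 reads in each library and 19 in all 15 distinct libraries, whereas its neighbours YPQ1 and RFC4 had 517 to 1043 and 203 to 326 reads. By group, the replicates had 0, 3 and 0 TRM10 reads in total mRNA with no RNA, 5, 4 and 2 in polysomal mRNA with no RNA, 0 and 1 in total mRNA with rancRNA_18, 1 in its polysomal library, 1, 0 and 2 in total mRNA with rancRNA_18-M2, and 0, 0 and 0 in its polysomal mRNA. A count of 0 allows up to 3 reads, counting error only, and 3 reads are 0.096 to 0.18 CPM over the depths of all 15 libraries. These counts do not measure how much of the electroporated RNA entered the cells. Structural and other noncoding RNAs were a small remainder after poly(A) selection, at 0.0145 to 0.0251% of reads in total and 0.0054 to 0.00829% in polysomal libraries.

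The first principal component held 33.6% of the variance and the second 21.1%. Libraries with the same replicate number lay together within a fraction, and the 3 electroporations did not separate.

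**Figure D1:**
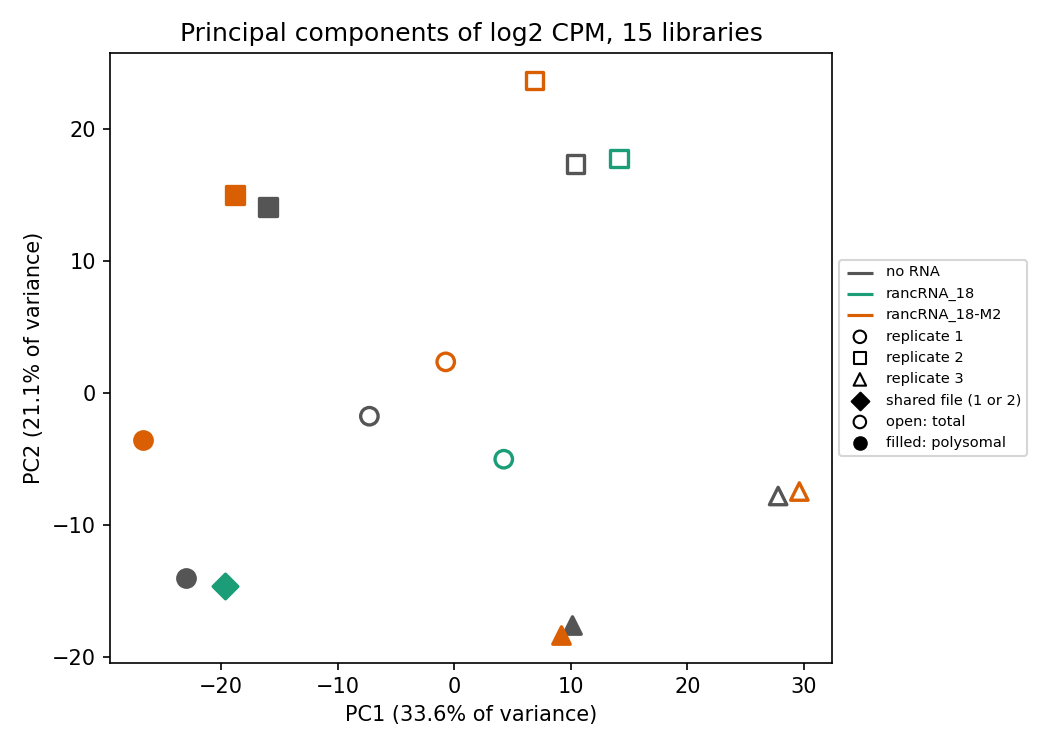
First against second principal component of log2 CPM (33.6% and 21.1% of the variance) for the 15 distinct libraries. Colour gives the electroporation, shape the replicate number, open symbols total and filled symbols polysomal mRNA, and the diamond is the library deposited under replicates 1 and 2. Libraries of one number and fraction lie close to each other whatever the electroporation.

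Whether rancRNA_18 alters the mRNA content of the cell was addressed by total mRNA. No gene of the 6106 tested passed for rancRNA_18 against no RNA (n = 2 against 3). HIS4, of histidine synthesis, had a log2 fold change of 0.46 (SE 0.21), with 173 ± 53.3 CPM (SD, n = 2) against 126 ± 5.82 CPM (SD, n = 3). ADE17, of purine synthesis, stood at 0.61 (SE 0.30) and FZF1 at 0.39 (SE 0.18). On the lower side TVP15 had -0.62 (SE 0.27), ISC10 -0.49 (SE 0.22) and DTD1 -0.57 (SE 0.26). The adjusted p of each of these genes was 1 by edgeR's quasi-likelihood test. Among gene groups, 16 of 17 glycolysis genes lay above 0, with a median log2 fold change of 0.34 and HXK2 at 0.46 (SE 0.24), TDH2 at 0.46 (SE 0.32), CDC19 at 0.41 (SE 0.30) and GPM1 at 0.38 (SE 0.29). None of them passed, over all genes or adjusted over the list alone. The list passed with the preset correlation (adjusted p = 1.4e-09) but not with an estimated correlation (adjusted p = 0.80). Amino acid biosynthesis genes had a median of 0.15, with 35 of 42 above 0 and 0 called, and an adjusted p of 1.9e-05 that became 0.80 with an estimated correlation. Noncoding RNAs had a median of -0.42, with 0 of 90 called, and an adjusted p of 1.4e-09 that became 0.25. Iron uptake genes had a median of -0.32 with 18 of 18 below 0 (adjusted p = 0.00084, and 0.80 with an estimated correlation), but the rancRNA_18 group has no replicate 3, and with the replicate block the median was 0. Of 32 lists, 8 passed with the preset correlation and 0 with an estimated one or by fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes. At an unadjusted p under 0.05 there were 27 genes in edgeR and 41 in DESeq2, which also called 0. With the replicate block 600 genes reached an unadjusted p under 0.05 and 0 were called.

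For rancRNA_18-M2 against no RNA in total mRNA (n = 3 against 3), 0 genes were called by edgeR and by DESeq2, in a fit that recovered 33% of simulated 2-fold changes (6072 genes). The genes with the smallest p were YJR115W at a log2 fold change of 0.54 (SE 0.22), YMR206W at 0.52 (SE 0.21) and PHO4, the phosphate-response transcription factor, at 0.54 (SE 0.25) on the higher side. ERP4 at -0.55 (SE 0.19), ERV41 at -0.38 (SE 0.14), both of vesicle traffic between endoplasmic reticulum and Golgi, and NSE5 at -0.41 (SE 0.16) were lowest. Glycolysis genes again lay above 0 in 16 of 17 cases (median 0.35, 0 called, with TDH2 at 0.51, SE 0.29, and TDH1 at 0.46, SE 0.26). The list's adjusted p of 2.2e-08 became 0.97 with an estimated correlation. The respiration list had a median of 0.12 and the amino acid list 0.11, both with an adjusted p of 0.97 with an estimated correlation, as had the noncoding RNAs at a median of -0.31. In all, 4 lists passed with the preset correlation and 0 otherwise. An unadjusted p under 0.05 was reached by 36 genes in edgeR, 56 in DESeq2 and 443 with the replicate block, where 0 were called.

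Set against each other in total mRNA, rancRNA_18 and rancRNA_18-M2 gave 0 called genes (n = 2 against 3). YGK1 (0.34, SE 0.17), CHO2, of phospholipid synthesis (0.48, SE 0.25), and SOF1 (0.22, SE 0.13) were the highest by p, and HAP3 (-0.36, SE 0.18), DPI8 (-0.57, SE 0.30) and ARG80 (-0.37, SE 0.20) the lowest. Ribosomal protein genes had a median log2 fold change of 0.05, which was -0.11 with the replicate block, so no direction is given for them. Ribosome biogenesis genes had a median of 0.10, with 62 of 76 above 0 and 0 called (adjusted p = 1.4e-05, and 0.77 with an estimated correlation). Of the lists, 8 passed with the preset correlation and 0 otherwise. Genes at an unadjusted p under 0.05 numbered 7 in edgeR, 14 in DESeq2, and 417 with the block, and 0 were called in each. The counts without the block lie below the share of 0.05 that unchanged genes would give, so they are no evidence of equal groups.

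Both comparisons with no RNA use the same control libraries. Their log2 fold changes in total mRNA correlated across genes with r = 0.62 (covariance 0.031), where unchanged groups simulated against those controls gave r = 0.45 (covariance 0.049), or r = 0.36 (covariance 0.016) with the replicate numbers in the simulation. In polysomal mRNA r was 0.18 (covariance 0.012), against 0.35 (0.048) and 0.24 (0.016). Genes are not independent replicates, and the control libraries were not split between the comparisons, so part of any excess may come from them. The number of genes called in both comparisons was 0 in each fraction. It could not be otherwise, since rancRNA_18-M2 against no RNA had 0 calls in either fraction.

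Polysomal mRNA shows which messages the ribosomes carried. With rancRNA_18 (n = 1, against 3 with no RNA) no gene passed, and this comparison rests on a single library whose spread is borrowed from the other groups. PBI2, an inhibitor of the vacuolar proteinase B, had a log2 fold change of 0.65 (SE 0.30), ADE17 0.79 (SE 0.37) and REX4 0.43 (SE 0.20). TIP1, a cell wall mannoprotein, had -1.21 (SE 0.60), GDE1 -0.40 (SE 0.19) and XDJ1 -0.44 (SE 0.22). Ribosomal protein genes lay above 0 in 133 of 137 cases, with a median of 0.31 and 0 called (adjusted p = 9.2e-19, and 0.57 with an estimated correlation), and this median was -0.02 in the block with the library taken as replicate 1 and 0.33 as replicate 2. Iron uptake genes had a median of -0.81, with 1 of 18 above 0 and 0 called, FIT3 at -1.45 (SE 0.95) and ARN1 at -1.50 (SE 1.03), and their adjusted p was 0.57 with an estimated correlation. With the library as replicate 1 their median was 0.04. Of the lists, 14 passed with the preset correlation and 0 with an estimated one. Genes at an unadjusted p under 0.05 numbered 22 in edgeR and 26 in DESeq2, which called 0.

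The replicate number of that library decides the blocked result. With the library as replicate 1, 0 genes passed (208 at an unadjusted p under 0.05) and 8 lists passed with the preset correlation, 0 with an estimated one. With it as replicate 2, 294 genes were higher and 232 lower with rancRNA_18 than with no RNA, among them ADE17 at 1.19 (adjusted p = 0.00018) and TIP1 at -1.71 (adjusted p = 1.2e-05), and the iron uptake list, at a median of -0.69 with 0 higher and 9 lower of 18 (1 and 13 adjusted over the list alone), passed with an estimated correlation (adjusted p = 0.0088). Against rancRNA_18-M2 (n = 1 against 3) the same library gave 0 calls without the block, 0 as replicate 1, and 455 higher and 413 lower genes as replicate 2, where iron uptake had a median of -0.77 (adjusted p = 0.012 with an estimated correlation). Without the block the genes with the smallest p in that comparison were DBP2, an RNA helicase, at 0.67 (SE 0.27), PHO5, an acid phosphatase, at 0.69 (SE 0.29) and RPA49 at 0.57 (SE 0.24), then YER053C-A at -0.76 (SE 0.29), ATM1 at -0.59 (SE 0.23) and XDJ1 at -0.53 (SE 0.22). It had 39 genes at an unadjusted p under 0.05 in edgeR, 51 in DESeq2 with 0 called, and 418 with the library as replicate 1. Proteasome genes lay above 0 in 32 of 34 cases (median 0.33, 0 called, adjusted p = 2.6e-09, and 0.45 with an estimated correlation), with a blocked median of 0.07 as replicate 1 and 0.58 as replicate 2, the latter with 21 higher (30 adjusted over the list alone) and an adjusted p of 0.13 with an estimated correlation. Ribosomal protein genes had a median of 0.18 without the block, -0.11 with it as replicate 1 and 0.23 as replicate 2, so no direction is given for them. Without the block 16 lists passed with the preset correlation and 0 with an estimated one, and with the block, as replicate 1, 8 and 0.

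For rancRNA_18-M2 against no RNA in polysomal mRNA (n = 3 against 3) no gene passed in edgeR or DESeq2, with 38 and 44 genes at an unadjusted p under 0.05, and with the block 0 of 417 such genes passed. RPS28B, a ribosomal protein gene with a near copy, had a log2 fold change of 0.44 (SE 0.18), with 543 ± 61.6 against 399 ± 57.5 CPM (SD, n = 3 each). YJR115W had 0.52 (SE 0.22) and TFB5 0.38 (SE 0.16). The lowest were PRM10 at -0.53 (SE 0.16), which overlaps another gene, ELO1, of fatty acid elongation, at -0.41 (SE 0.13) and GET1 at -0.43 (SE 0.16). Ribosome biogenesis genes had a median of -0.10 with 13 of 76 above 0, NOP56 at -0.50 (SE 0.22), NOP58 at -0.34 (SE 0.18), and 0 called. The list's adjusted p of 1.3e-06 became 0.91 with an estimated correlation. tRNA synthetase genes had a median of -0.13 with 2 of 19 above 0 (adjusted p = 0.00055, and 0.91 with an estimated correlation). With the preset correlation 8 lists passed, and 0 with an estimated one.

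Polysomal was set against total mRNA to see which messages were relatively higher in polysomes. Shorter coding sequences tended to be higher in this comparison (Spearman rho -0.36 with coding length across 5744 genes, no RNA). That trend was removed only for ribosomal protein genes, so length was not separated from loading for the other lists and genes. In cells without RNA (n = 3 against 3), 119 of 137 ribosomal protein genes and 22 of 44 respiration genes were higher in polysomes with the replicate block (89.8% and 24 adjusted over the list alone), and 37 of 90 noncoding RNAs were lower (48 adjusted over the list alone). As lists, none of these passed with an estimated correlation in that fit (adjusted p = 0.21, 0.52 and 0.11). In all, 753 genes were higher and 579 lower. Without the block, as planned, 0 were higher and 12 lower. Leaving out 1 library reduced the 1332 calls with the block to 750 (without total replicate 3), and the 12 without it to 4 (without polysomal replicate 2). DESeq2 without the block called 42 higher and 66 lower. At an unadjusted p under 0.05 there were 648 genes without and 2015 with the block. The calls described next are those of the blocked fit.

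Of 137 ribosomal protein genes, 119 rose (86.9%) and 1 fell in polysomes with no RNA, 89.8% and 3 genes adjusted over the list alone, with a median log2 fold change of 0.63. RPL20B (0.82, SE 0.11), RPL20A (0.78, SE 0.11), RPS18A (0.79, SE 0.12) and RPL40B (0.77, SE 0.11) were the members with the smallest p. Respiration and tricarboxylic acid cycle genes had a median of 0.36, with 22 higher and 1 lower of 44 (24 and 2 adjusted over the list alone), among them the oxidase subunit COX12 at 0.78 (SE 0.13) and the ATP synthase subunit ATP17 at 0.74 (SE 0.13). Histone genes had a median of 0.25, with 4 of 10 higher (4 adjusted over the list alone), as HTZ1 at 0.43 (SE 0.10). Ribosome biogenesis genes had a median of -0.21, with 1 higher and 23 lower of 76 (1 and 27 adjusted over the list alone), as EBP2 at -0.67 (SE 0.10) and ENP1 at -0.55 (SE 0.09). Of 23 chaperone genes 8 were lower and 1 higher (the same adjusted over the list alone), with STI1 at -0.49 (SE 0.11), SSA2 at -0.53 (SE 0.12), and the small mitochondrial co-chaperonin HSP10 at 0.57 (SE 0.11). Glycolysis genes had a median of -0.42 with 5 of 17 lower (7 adjusted over the list alone), as the enolases ENO1 at -0.71 (SE 0.16) and ENO2 at -0.65 (SE 0.17). Of 19 tRNA synthetase genes 6 were lower (7 adjusted over the list alone), as DPS1 at -0.58 (SE 0.15). Noncoding RNAs had a median of -1.71, with 37 of 90 lower (48 adjusted over the list alone), as the small nucleolar RNA snR30 at -3.73 (SE 0.33) and the spliceosomal RNA LSR1 at -3.37 (SE 0.32). Together, noncoding RNAs held 0.022 to 0.0251% of reads in total and 0.00572 to 0.00829% in polysomal libraries with no RNA. These changes thus concern a small remainder after poly(A) selection.

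As lists, 13 of 32 passed with the preset correlation in the blocked fit and 0 with an estimated correlation. The adjusted p with an estimated correlation was 0.21 for ribosomal proteins, 0.52 for ribosome biogenesis, respiration, histones and chaperones, 0.54 for tRNA synthetases, 0.61 for glycolysis and 0.11 for noncoding RNAs. By fry the adjusted p was 0.0022 for ribosomal proteins, 0.032 for ribosome biogenesis, 0.029 for respiration, 0.036 for histones, 0.024 for chaperones, 0.029 for tRNA synthetases, 0.12 for glycolysis and 0.0022 for noncoding RNAs. Without the block the noncoding RNAs, with 8 of 90 called (32 adjusted over the list alone), were the list that passed with an estimated correlation (adjusted p = 0.0026) and by fry (0.00071), and no ribosomal protein gene passed.

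Single genes with the largest rise in polysomes of cells without RNA included the thioredoxin genes TRX2, at 1200 ± 23.1 against 637 ± 168 CPM (SD, n = 3 each; log2 fold change 0.94, SE 0.13), and TRX1 (0.86, SE 0.16). The others were OST5, of protein glycosylation (0.93, SE 0.29), ECM15 (0.91, SE 0.13), PBI2 (0.90, SE 0.15), MRA1 (0.89, SE 0.13), NTF2, of nuclear import (0.86, SE 0.14), the vacuolar ATPase subunit VMA7 (0.85, SE 0.13), the initiation factor eIF1A gene TIF11 (0.85, SE 0.11), and the ribosomal genes RPS10B (0.92, SE 0.14), RPS10A (0.89, SE 0.14) and RPS17A (0.87, SE 0.17), each of which has a near copy. HAC1, encoding the transcription factor of the unfolded protein response, fell by 1.23 (SE 0.17) on the log2 scale, from 153 ± 59.6 CPM in total to 65.2 ± 27.2 CPM in polysomal mRNA. NPL3, an mRNA-binding protein, fell by 0.98 (SE 0.22), the cell surface protein gene TOS6 by 1.17 (SE 0.11), the transporter gene AQR1 by 1.13 (SE 0.15), the snoRNP assembly factor NAF1 by 0.95 (SE 0.11), the aquaporin AQY1 by 0.95 (SE 0.12), MRPL32 by 0.90 (SE 0.10) and SKS1 by 0.89 (SE 0.13). YGR079W (-1.07, SE 0.13), YOR338W (-1.06, SE 0.12), YKL068W-A (-1.02, SE 0.18) and YGR035C (-0.91, SE 0.13) complete the list. The largest adjusted p among these genes was 0.038, for OST5, in the blocked edgeR fit. Without the block, the 12 genes that fell were TOS6 (-1.18, SE 0.20, adjusted p = 0.022), LSR1, snR30, snR31, snR33, snR44, snR86, snR9, the telomerase RNA TLC1, MIN10, YBR090C, which overlaps another gene, and YDR241W. TRX2 (0.91, SE 0.21), PBI2 (0.90, SE 0.22) and RPC11 (0.84, SE 0.20) were then the highest, each with an adjusted p of 0.17.

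**Figure D2:**
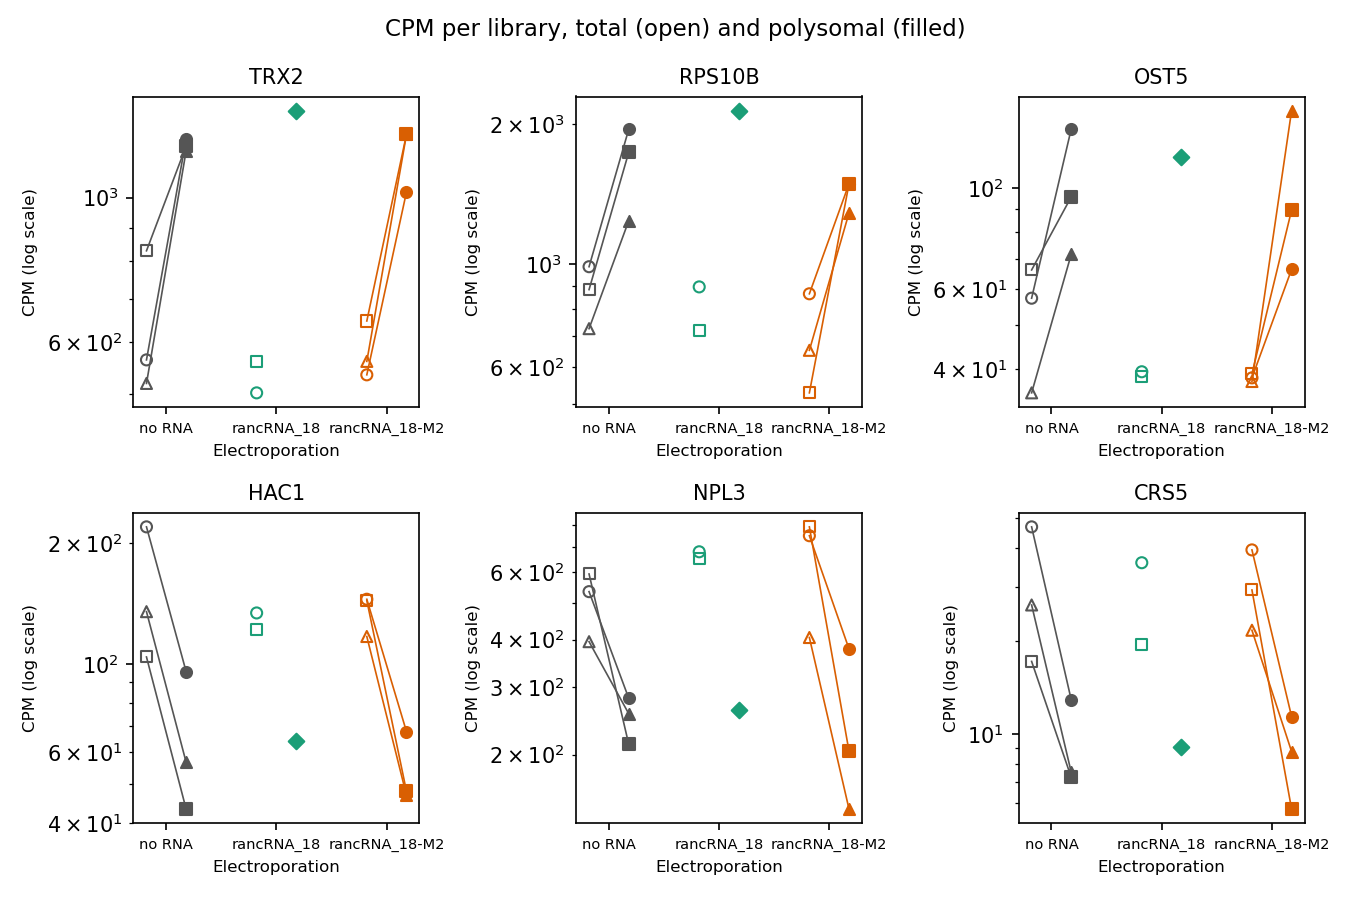
CPM per library on log axes for TRX2, RPS10B and OST5, higher in polysomal mRNA, and HAC1, NPL3 and CRS5, lower. Open symbols are total and filled symbols polysomal libraries, circles, squares and triangles are replicates 1, 2 and 3, lines join the same number, and the diamond is the single rancRNA_18 polysomal library. In the 2 electroporations with pairs, each line runs the same way in all 3 pairs of every gene shown. Genes were named only if every pair of the naming comparison had the same direction, so this follows in part from the choice.

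With rancRNA_18-M2 (n = 3 against 3), 1023 genes were higher and 916 lower in the blocked fit, and 0 lists passed with an estimated correlation. Without the block the counts were 5 and 18 in edgeR and 239 and 172 in DESeq2. At an unadjusted p under 0.05 there were 1055 genes without and 2499 with the block. Ribosomal protein genes had a median of 0.80, with 89.8% of 137 higher and 0 lower (124 and 2 genes adjusted over the list alone), as RPS25A at 1.14 (SE 0.14) and RPL26B at 1.04 (SE 0.13). Respiration genes had 23 higher and 4 lower of 44 (24 and 7 adjusted over the list alone), and ribosome biogenesis 2 higher and 39 lower of 76 (2 and 42) with a median of -0.31. All 19 tRNA synthetase genes lay below 0, with 14 lower (18 adjusted over the list alone), as KRS1 at -0.61 (SE 0.11). Histones had 5 higher of 10 (6 adjusted over the list alone). Chaperones had 13 lower and 1 higher of 23 (15 and 1 adjusted over the list alone), as SSA1 at -0.77 (SE 0.13), and glycolysis 12 lower of 17 (13) with a median of -0.59. Noncoding RNAs had a median of -1.20 with 30 of 90 lower (30 adjusted over the list alone). OST5 (1.42, SE 0.30), LSM2 (1.23, SE 0.27), YBR013C (1.23, SE 0.20), MRA1 (1.22, SE 0.13) and YGR182C (1.21, SE 0.23) rose most, and DDR48 (-1.54, SE 0.46), NPL3 (-1.45, SE 0.22), HAC1 (-1.35, SE 0.17), SRL1 (-1.32, SE 0.16) and AQR1 (-1.26, SE 0.15) fell most. Of the lists 18 passed with the preset correlation and 0 with an estimated one, where the adjusted p was 0.29 for ribosomal proteins and noncoding RNAs and 0.44 for ribosome biogenesis, tRNA synthetases, chaperones, glycolysis, histones and respiration. By fry 21 passed. Without the block the named genes that passed were the copper chaperone gene ATX1 (1.13, SE 0.20), PBI2 (1.12, SE 0.22), RPC11 (1.10, SE 0.20), AIM29 (1.05, SE 0.19) and TRS33 (0.65, SE 0.12), higher, and TOS6 (-1.12, SE 0.20), NAF1 (-1.02, SE 0.18), DBP2 (-1.01, SE 0.20), MRPL32 (-1.01, SE 0.19) and SUR7 (-0.74, SE 0.14), lower. Noncoding RNAs then had 7 of 90 lower (18 adjusted over the list alone), and ribosomal proteins 0 higher (76 adjusted over the list alone). The noncoding list had an adjusted p of 0.046 with an estimated correlation. Leaving out single libraries moved the 23 calls from 3, without polysomal replicate 2, to 70, without polysomal replicate 1.

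With rancRNA_18 the comparison has 1 polysomal library against 2 total libraries. Without the block 0 genes passed in edgeR (503 at an unadjusted p under 0.05) and 47 in DESeq2 (38 higher, 9 lower). With the block and the library as replicate 1, 508 were higher and 240 lower, and as replicate 2, 987 and 833. Leaving out a rancRNA_18 total library reduced the 748 calls as replicate 1 to 158 (without replicate 1) or 219 (without replicate 2). As replicate 1, ribosomal protein genes had a median of 0.78 with 101 higher and 0 lower of 137 (117 and 0 adjusted over the list alone). Chaperones had 7 lower and 1 higher of 23 (13 and 1), histones 3 higher of 10 (5), and noncoding RNAs 14 lower of 90 (19) with a median of -1.26. As replicate 2, ribosomal protein genes had a median of 1.07 with 127 higher (131 adjusted over the list alone), chaperones 9 lower and 3 higher (11 and 3), histones 9 higher (9), and noncoding RNAs 20 lower (20), with adjusted p of 0.15, 0.81, 0.15 and 0.47 with an estimated correlation. As replicate 1 that adjusted p was 0.44 for ribosomal proteins and 0.56 for the other 3 lists. Iron uptake had 1 gene higher and 1 lower of 18 as replicate 1, and 1 higher and 13 lower as replicate 2 (the same adjusted over the list alone), there with a median of -0.93 and an adjusted p of 0.022 with an estimated correlation. OST5 (1.58, SE 0.44), TRX2 (1.48, SE 0.19), DTD1 (1.41, SE 0.28), ATX1 (1.32, SE 0.21) and NTF2 (1.31, SE 0.20) rose most as replicate 1, and the metallothionein gene CRS5 (-1.99, SE 0.29), NPL3 (-1.46, SE 0.35), ADH2 (-1.35, SE 0.28), HAC1 (-1.29, SE 0.28) and EMA17 (-1.25, SE 0.27) fell most. Without the block ATX1 had 1.34 (SE 0.28), TRX2 1.35 (SE 0.30), AIM29 1.25 (SE 0.27), EMA17 -1.46 (SE 0.37), SSA4 -0.83 (SE 0.23) and COX18 -1.31 (SE 0.36), none of which passed.

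In the blocked fits, 723 genes were higher in polysomes both with no RNA and with rancRNA_18-M2, where independent lists would share 126.2, and 490 were lower in both, where they would share 86.9. No gene was called in opposite directions. The calls with no RNA and rancRNA_18, as replicate 1, shared 466 higher (62.6 for independent lists) and 202 lower genes (22.8). The groups compared hold different libraries, but the comparisons share 1 estimate of the spread and the terms for the replicate numbers. For rancRNA_18, whose fractions are not paired by number, those terms enter the fold change itself, and its calls rest on 1 polysomal library.

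**Figure D3:**
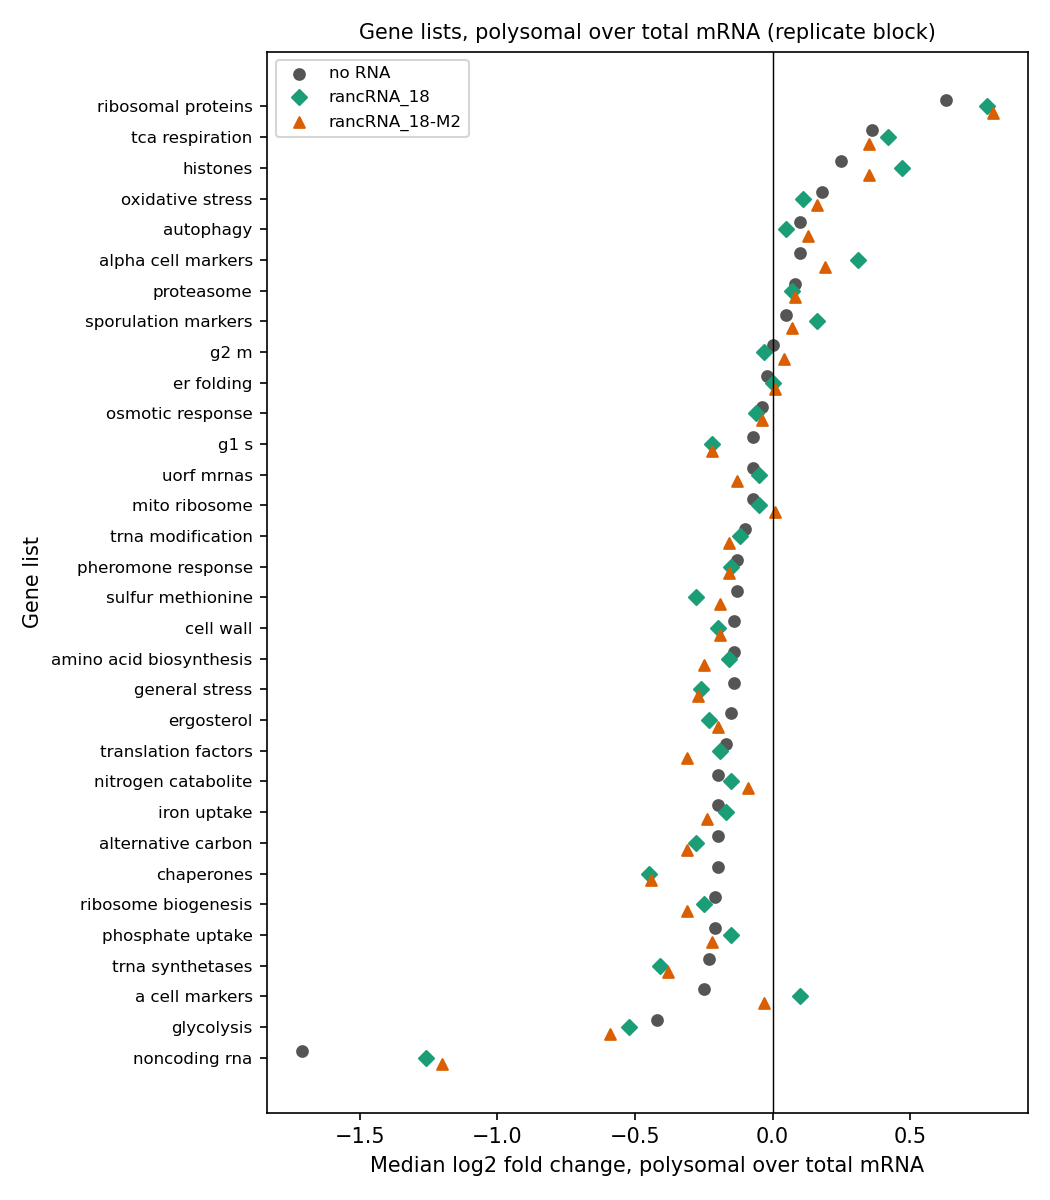
Median log2 fold change, polysomal over total mRNA, of each of the 32 gene lists with tested members, from the fit with the replicate block, for the 3 electroporations (rancRNA_18 library taken as replicate 1). Ribosomal protein genes have medians of 0.63, 0.78 and 0.80 with no RNA, rancRNA_18 and rancRNA_18-M2, and noncoding RNAs -1.71, -1.26 and -1.20. Medians say nothing of the spread of single genes or of the tests, which the text gives.

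Whether the electroporated RNA changed the loading itself was tested by the difference between electroporations in the polysomal to total ratio. Recovery of known changes was not simulated for these contrasts. Their median SE was 0.32 to 0.41 without the block and 0.17 to 0.22 with it. For rancRNA_18-M2 against no RNA within a fraction it was 0.23 and 0.12. Counts of 0 here therefore do not show that loading was unchanged. For rancRNA_18-M2 against no RNA 0 genes passed in edgeR (13 at an unadjusted p under 0.05), in DESeq2 (18) and with the block (77). TOM7 (0.67, SE 0.33), YER053C-A (0.53, SE 0.27) and TFB5 (0.42, SE 0.22) were highest by p, and BUL1 (-0.35, SE 0.18), ERB1 (-0.30, SE 0.19) and PMI40 (-0.47, SE 0.30) lowest. Ribosomal protein genes had a median of 0.16, with 127 of 137 above 0 and 0 called (adjusted p = 1.8e-05, and 0.92 with an estimated correlation), and all 19 tRNA synthetase genes lay below 0 (median -0.17, 0 called, adjusted p = 1.2e-05, and 0.64 with an estimated correlation). In all 11 lists passed with the preset correlation and 0 with an estimated one.

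For rancRNA_18 against no RNA the ratio contrast gave 0 calls in edgeR (15 at an unadjusted p under 0.05), 0 in DESeq2 (25) and 0 with the block and the library as replicate 1 (60), but 101 higher and 68 lower as replicate 2. Against rancRNA_18-M2 the counts were 0 (12), 0 (19), 0 (33), and 96 higher and 63 lower. Iron uptake was again the list that passed with an estimated correlation as replicate 2, with medians of -0.70 (adjusted p = 0.0086) and -0.77 (adjusted p = 0.0049). The same list separated the libraries numbered 2 from those numbered 1, with a median of 0.73 and an adjusted p of 0.0025 with an estimated correlation. ARN1, chosen after its values were seen, stood at 27 CPM in the single rancRNA_18 polysomal library, against 28.2 and 33.1 CPM in the polysomal libraries of replicate 1 and 77.8 and 68 CPM in those of replicate 2. LDB18 (0.66, SE 0.30), COQ11 (0.50, SE 0.25) and TVP15 (0.81, SE 0.42) were highest by p against no RNA, with FYV8 (-0.45, SE 0.24), XDJ1 (-0.52, SE 0.27) and NPP1 (-0.83, SE 0.47) lowest. Against rancRNA_18-M2 these were YPL039W (0.47, SE 0.23), CGI121 (0.57, SE 0.30) and LRS4 (0.42, SE 0.27), then ATM1 (-0.61, SE 0.29), SNU66 (-0.56, SE 0.30) and NPP2 (-0.52, SE 0.29). Ribosomal protein genes had a median of 0.30 against no RNA with 136 of 137 above 0 and 0 called (adjusted p = 2.2e-13, and 0.84 with an estimated correlation). With the block their median was 0.14 as replicate 1 and 0.48 as replicate 2 (adjusted p = 0.84 and 0.34 with an estimated correlation). Lists passing with the preset correlation numbered 8 and 10, none of which passed with an estimated correlation. With the block and the library as replicate 1 these numbers were 6 and 0.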

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

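The counts in this part come from an alternative added after the data were examined, and both tests of them were set before their results were seen. In the fit with the replicate block and the shared rancRNA_18 polysomal library taken as replicate 2, the polysomal to total ratio differed between electroporations, by the test of the difference itself, in 169 genes for rancRNA_18 against no RNA and in 159 genes for rancRNA_18 against rancRNA_18-M2. With the library as replicate 1, or without the block, both counts were 0.

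The calls that appear with the library as replicate 2 were weighed between a library that belongs to replicate 1 and an effect of rancRNA_18 on polysomal mRNA. The deviation of the shared library from the other polysomal libraries was set against the difference between replicates 1 and 2 in total mRNA, and its slope was 0.38. The known polysomal libraries of replicate 1 had slopes of 0.44 and 0.39 and those of replicate 2 had -0.44 and -0.39, so the shared library lay far from replicate 2 and just under the range of replicate 1 that the prediction required. ARN1, chosen after its values were seen, was likewise near replicate 1, as described with the ratio contrasts. On the second principal component the shared library lay at -14.65. The polysomal libraries of replicate 1 lay at -14.04 and -3.58 there, and those of replicate 2 at 14.1 and 14.99. The slope, taken over all genes, and this position argue against number 2 for the shared library. The calls as replicate 2 therefore cannot be read as an effect of rancRNA_18. That the file is of replicate 1 was not met in full as predicted, and the range rests on 2 libraries. An effect of rancRNA_18 stays open, since the group holds 1 distinct polysomal library where its prediction required at least 2.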

How the results depend on the processing

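The alternatives with the shared library as replicate 2, with both copies counted and with the blocked fit as the starting point were chosen after seeing the data. Libraries were left out in turn apart from the shared library, and each only for the contrasts that hold its group. Contrasts that rest on the shared library were thus not tested for their dependence on it. Between electroporations, all 9 counts of called genes stayed at 0 under DESeq2, other size factors, no filter, only the groups compared, the replicate block with the shared library as replicate 1, and each library left out (0 to 0). They moved for rancRNA_18 in polysomal mRNA when that library was taken as replicate 2 in the block, to 526 against no RNA and 868 against rancRNA_18-M2, with 169 and 159 for the ratio and 158 and 151 with a block per culture. With both copies counted in the block the polysomal counts were 2 and 305. The slope of 0.38 argues against number 2 for that library, so the calls as replicate 2 cannot be read as an effect of rancRNA_18. Such an effect stays open, with 1 distinct library. No gene was called for both rancRNA_18 and rancRNA_18-M2 against no RNA under the alternatives run. Where rancRNA_18-M2 had 0 calls this could not come out otherwise, so it says nothing of a shared effect. Polysomal against total mRNA, with 12, 0 and 23 calls for no RNA, rancRNA_18 and rancRNA_18-M2, gave 108, 47 and 411 with DESeq2, 4, 49 and 5 with only the groups compared, 1332, 748 and 1939 with the replicate block, 1332, 1820 and 1939 with the shared library as replicate 2, and 1459, 484 and 2056 with a block per culture (1459, 1574 and 2056 as replicate 2). Both copies counted gave 38 and 103 for rancRNA_18 and rancRNA_18-M2, and with the block 1193, 1754 and 1820. The cause was not tested, except that a block removes the spread between replicate numbers. Leaving out 1 library gave 4 (without polysomal replicate 2, and likewise without polysomal replicate 3) to 10 for no RNA, 0 to 0 for rancRNA_18, and 3 (without polysomal replicate 2) to 70 (without polysomal replicate 1) for rancRNA_18-M2, with 4, 6 and 12 without total replicates 1, 2 and 3 and 7 without polysomal replicate 3. From the blocked counts of 1332, 748 and 1939, the fit without the block gave 12, 0 and 23. For rancRNA_18 the block per culture gave 484, the shared library as replicate 2 gave 1820 and both copies 1754. Leaving out 1 library in the blocked fit gave 750 (without total replicate 3) to 1306 for no RNA, with 794 without polysomal replicate 2, then 158 (without total replicate 1) to 219 (without total replicate 2) for rancRNA_18, and 1332 (without polysomal replicate 2) to 2106 for rancRNA_18-M2. Apart from the block per culture with the shared library as replicate 2, given above for rancRNA_18, other alternatives to the blocked counts stayed within 1.5 times. Of the 74 gene results named by the fixed rule, 11 were called, and of their 176 alternatives 104 kept the call, 72 lost it and 0 reversed it. The other 63 were not called, and of their 922 alternatives 841 stayed uncalled and 81 gained a call. Of 566 alternatives to the 44 gene results named from the blocked fit, 503 kept the call, 63 lost it and 0 changed direction. Gene lists passing with the preset correlation, 8, 4 and 8 in total mRNA (rancRNA_18 against no RNA, rancRNA_18-M2 against no RNA, and rancRNA_18 against rancRNA_18-M2), 14, 8 and 16 in polysomal mRNA, 8, 11 and 10 for the ratio, and 9, 11 and 18 for polysomal against total mRNA, became 0 with an estimated correlation and by fry, except 1 and 1 with no RNA and 1 and 4 with rancRNA_18-M2 in the last. The cause was not tested. With the block, the lists became 8 and 8 for rancRNA_18 in polysomal mRNA, 0 for the ratio of rancRNA_18 against rancRNA_18-M2, and 13 and 18 for the ratios with the library as replicate 2. By fry, the lists passing for polysomal against total mRNA became 14, 6 and 21 with the block, and the noncoding RNAs no longer passed with an estimated correlation with no RNA (adjusted p = 0.11) or rancRNA_18-M2 (adjusted p = 0.29). The remaining counts of genes, and of lists with the preset correlation, stayed within 1.5 times with the block and the library as replicate 1. In simulated data without the block, at most 2% of 1.5-fold and 38.8% of 2-fold changes were recovered, and 0% of either for rancRNA_18 against no RNA in polysomal mRNA, so counts of 0 without it leave changes of both sizes open. With the block, where the counts for rancRNA_18-M2 against no RNA were also 0, 75.8% and 91% were recovered in total and 80% and 90.8% in polysomal mRNA. Those counts were drawn from the blocked model itself, so they limit the changes that went unseen only as far as that model holds.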

Other observations

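The comparison of replicate numbers, its correction for length and GC content and its random renumbering were chosen only after the pairing was seen, and the tests of the ribosomal protein genes and of the splits were set before their results. Replicate numbers are not groups of the study, and values here come from the fit with group and number over all 15 libraries. Between at least 1 pair of numbers 4471 of 6106 genes differed, by a joint test over libraries of both fractions and all electroporations. The contrasts between electroporations in the same fit, with the shared library as replicate 1, gave 0 genes. They compare fewer libraries, so the counts are not on equal terms. Total and polysomal libraries counted as separate libraries of a number, so the SEs given here may be too small. Genes of iron uptake, the siderophore transporters, ferroxidase and cell wall mannoproteins that yeast uses when iron is scarce, stood out. In libraries numbered 3 against 1 their median log2 fold change was 1.40, with 17 higher and 0 lower of 18 and an adjusted p of 9e-04 with an estimated correlation, as ARN1 at 2.03 (SE 0.09), ARN2 at 2.01 (SE 0.08) and FIT3 at 1.76 (SE 0.13). Libraries numbered 2 against 1 had a median of 0.73 with 14 of 18 higher (adjusted p = 0.0025), as FET3 at 1.53 (SE 0.09), and 3 against 2 a median of 0.56 with 16 of 18 higher (adjusted p = 0.074). The gene of inositol phosphate synthase, INO1, was -2.41 (SE 0.11) in 2 against 1 and 2.20 (SE 0.12) in 3 against 2. The amino acid transporter gene DIP5 was 2.72 (SE 0.10) and the transporter gene AQR1 2.33 (SE 0.13) in 3 against 1, and the wall protein genes PIR3 and CWP2 were -2.54 (SE 0.13) and -2.13 (SE 0.12) in 3 against 2. All 8 genes of the G2/M list were higher in 3 against 2 (median 0.61), with an adjusted p of 0.33 with an estimated correlation. Ribosomal protein genes had a median of -0.67 in 3 against 1, with 129 of 137 lower and an adjusted p of 0.75 with an estimated correlation.

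The most abundant mRNAs were those of the glycolytic enzymes TDH3, at a mean of 21800 CPM, FBA1 at 15600 CPM and GPM1 at 13400 CPM, and of the stress protein HSP12 at 19300 CPM. HSP12 ranged from 10300 to 16500 CPM in total and from 20400 to 33500 CPM in polysomal libraries. The galactose genes GAL1, GAL7 and GAL10 were at 2770 to 6580, 2900 to 5420 and 2030 to 4760 CPM. FIT2, a wall protein of iron uptake, was at 2060 to 9340 CPM. Among markers of mating type, the alpha-factor gene MF(ALPHA)1 was at 50.5 to 254 CPM and STE3 at 14.1 to 22.8 CPM, against 0.886 to 1.70 CPM for MFA1, 0.244 to 1.06 CPM for MFA2 and 2.27 to 4.94 CPM for STE2.

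The differences between replicate numbers were weighed against length and GC bias and against chance. Across 5744 genes the change in 3 against 1 followed coding length (Spearman rho 0.64) and GC content (rho -0.38), where genes are not independent replicates. With the length and GC trends of each library removed, 3991 genes still differed, against 4346 of the same genes before, which argues against these trends as the whole cause. Random numberings within the groups reached as many genes in 1 of 60 cases, the real one included, and the highest other gave 1325. Each group was renumbered on its own. This also unlinked total from polysomal libraries of the same electroporation and number, which correlated at r from 0.57 to 0.794. The numberings therefore cannot exclude chance for a link of the numbers across electroporations, and they were run after the pairing was seen. A shared day, culture or library batch per number stays open, since the labels name none, and no biological explanation was tested.

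Ribosomal protein genes were higher in polysomal than in total mRNA in all 6 pairs of known number, with a mean of the medians of 0.69 (SD 0.18), and short coding sequences tended to be higher. In the 1443 shortest genes, of 26 to 240 codons, the median log2 fold change with no RNA was 0.28 (588 higher and 54 lower), against -0.08 in the 1435 genes of 637 to 4911 codons (11 higher and 115 lower), and across 5744 genes rho with coding length was -0.36, -0.42 with rancRNA_18-M2 and -0.42 with rancRNA_18. With the length trend of the other genes removed the ribosomal protein median was 0.44 (SD 0.12), and with the GC trend removed 0.74 (SD 0.16), each over 0 by more than 2 SD, which argues against either trend as the whole cause, though part of the size goes with length. The 19 ribosomal protein genes without an A or B copy had 0.66 (SD 0.14), which argues against reads shared between copies. A difference in ribosome loading may underlie what is left, as a hypothesis found and tested on the same libraries, and RNA quality or the choice of gradient fractions was not tested.

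With the real one included, the same 6 libraries have 10 splits, or 4 when libraries are swapped within pairs, too few for a share under 0.05. Without the block, polysomal against total mRNA gave 12 genes with no RNA, as did 1 of 10 splits, the real one, with 1 gene in the highest other, and 23 with rancRNA_18-M2, again 1 of 10, with 0 in the highest other. With the block the counts were 1332 and 1939, each reached in 1 of 4 splits, with 0 in the highest other. For rancRNA_18-M2 against no RNA the real count was 0, which all 10 splits reach whatever the data, so the splits say nothing there (highest other 0 in total mRNA, 4 in polysomal mRNA and 0 for the ratio).

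For the lists not described above, blocked medians of polysomal over total mRNA with no RNA were 0.18 for oxidative stress (6 higher and 4 lower of 21), 0.10 for autophagy (4 and 0 of 18) and 0.08 for the proteasome (5 and 0 of 34). Lower medians were found for alternative carbon use at -0.20 (0 higher and 5 lower of 24), phosphate uptake at -0.21 (1 and 5 of 16), iron uptake at -0.20 (2 and 6 of 18), nitrogen catabolite genes at -0.20 (1 and 5 of 21), translation factors at -0.17 (4 and 6 of 38), ergosterol synthesis at -0.15 (0 and 3 of 24), general stress at -0.14 (4 and 8 of 34), cell wall at -0.14 (2 and 4 of 35), amino acid synthesis at -0.14 (3 and 8 of 42), sulfur and methionine genes at -0.13 (0 and 7 of 21) and tRNA modification at -0.10 (2 and 8 of 37). Mitochondrial ribosome genes had -0.07 (7 and 9 of 68) and endoplasmic reticulum folding genes -0.02 (2 and 5 of 16). The smaller lists had -0.25 for a-cell markers (0 and 0 of 7), -0.13 for pheromone response (1 and 2 of 13), -0.07 for mRNAs with upstream reading frames (0 and 1 of 9) and for the G1/S list (0 and 1 of 14), -0.04 for osmotic response (2 and 3 of 15), 0 for the G2/M list (0 and 0 of 8) and 0.05 for sporulation markers (1 and 0 of 15). The alpha-cell markers had 0.10 (0 and 1 of 4), where the test pointed lower. The adjusted p with an estimated correlation was at least 0.52 for each of these lists.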
